A study of Daphnia magna with 15 samples.

How the data were processed

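Total RNA of whole animals was labelled with Cy3 and hybridised to Agilent arrays of 60-base probes. Per the file headers, the deposited intensity values came from Agilent Feature Extraction, version 10.5.1.1 for 8 arrays and 10.7.3.1 for 7, while the submitters' processing notes name version 10.5. The arrays lay on 5 slides and were read by 2 scanners. Each slide held 2 to 4 arrays, and each scanner read arrays of all 5 groups. Control and mixture arrays shared only slide 2, and diazepam and propranolol arrays shared no slide. A slide block therefore compares these groups largely through the others. Scanner, software version and the 25 or 60 columns of the file coincide fully, so that a scanner block stands for all of them. The processed intensity is background-subtracted and detrended by that software, per the file headers. Quality flags, deposited with the intensities by the authors as other columns, were used as given.

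A table of the authors' processed values was used as an alternative. Its deposited values behave as log2 values centred on each probe: set against the scanner values, differences between arrays had slopes of 0.967 to 1.03. The column medians lay between -0.0101 and 0.00913. How it was scaled and filtered is not given in the sources used here. In 64 of its probes, 51 of them tested, 1 group held exactly the same value on all 3 arrays.

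Control spots and spots flagged as outliers (81 to 343 per array) were left out, and spots of one probe were averaged. No spot was marked saturated, with control spots not counted. Since under 50 percent of probes were detected, log2 intensity was scaled by subtracting each array's 75th percentile over the 8614 probes well above background on all 15 arrays. A probe was tested if it was well above background on all 3 arrays of at least 1 group. Group means were fitted to all 15 arrays in limma 3.58.1 (R 4.3.3), with 10 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Other tests used Python 3.11.15 with scipy 1.17.1. The mixture was compared with each drug, with the mean of the drugs and with the control, and the drugs with the control and each other. Samples were grouped by their titles and treatment labels, which write diazepam as diazepan.

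The rule for naming probes, the designs and most alternatives were fixed before the data were examined. No probe identifier matched the 28335 genes of the reference table and every description read unknown, so the 29 planned gene lists and their tests could not be run. The rule was then applied to each exposure against control and to the mixture against the mean of the drugs. It took the 2 higher and 2 lower probes of smallest p whose 3 exposed arrays lay on one side of the reference mean. That reference was the control, or the mean of the 3 drug groups in the last comparison. On data simulated for the mixture against control over 11983 probes, the fit recovered 4.0% of probes changed by 0.5 on the log2 scale, 36.8% at 1, 75.2% at 2 and 88.0% at 3, and 4.14% of its calls were false. Simulated probes varied independently, unlike the probe set that moved together in these arrays.

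Alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, no filter and a stricter filter on dim probes, slide, scanner and replicate number as blocks, only the groups compared, the authors' table, array weights, an intensity trend, and leaving out each array. Normexp used median in place of mean signal, which the compact files lack. Scaling by all probes, spike-in scaling by 5 probes, the authors' table without repeated values, and settings of the 6-array fit were chosen after seeing the data. So were the tests on the probes lower in the mixture, on spike-in signal, on negative controls and on consecutive identifiers.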

Results

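Whole-body RNA of 4-day-old females of the water flea Daphnia magna was measured on 15 one-colour arrays, 3 for each of 5 groups. The groups were a solvent control, carbamazepine at 1 µg/L, diazepam at 0.1 µg/L, propranolol at 0.1 µg/L, and a mixture of the 3 drugs. Carbamazepine is an anticonvulsant, diazepam a benzodiazepine and propranolol a beta-adrenergic blocker. The concentration of each drug within the mixture was not given in the sources used here. Each array carried 51424 probes, of which between 22.4% and 26.3% gave a signal well above background, and 12036 probes met the detection filter and were tested. The number of arrays limits the precision. The median 95% confidence interval of a log2 change against control reached 0.60 to either side. Part of this spread came from mixture replicate 5, which had the lowest array weight (0.15, against 0.79 to 2.01 for the others). Without it the median residual SD of the control and mixture arrays fitted alone was 0.23, against 0.35 with it. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. The probes carry no gene names, and each is named here by its identifier and sequence.

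The first comparison asked whether any probe differed among the 5 groups. In limma's moderated F test no probe passed an adjusted p of 0.05, and the smallest adjusted p was 0.989. At an unadjusted p under 0.05 there were 560 probes, against 602 expected by chance, and a one-way analysis of variance without moderation also called 0. The first principal component held 37.1% of the variance. The 3 mixture arrays scored 49.96 ± 20.5 (SD, n = 3) on it and the 3 control arrays -35.3 ± 17.8 (SD, n = 3), with no overlap. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. The difference was 113.9 on scanner 1 and 62.2 on scanner 2. Carbamazepine replicate 4 scored 67.8 and propranolol replicate 2 scored 38.1, inside the range of the mixture arrays. Over all probes the 5 groups accounted for 31.7% of the squared distance between arrays (permutation p = 0.279, and 0.202 when permuted within scanner). Set against all other arrays in 5 exact tests, the mixture stood farthest apart (exact p = 0.0264, adjusted p = 0.132).

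**Figure D1:**
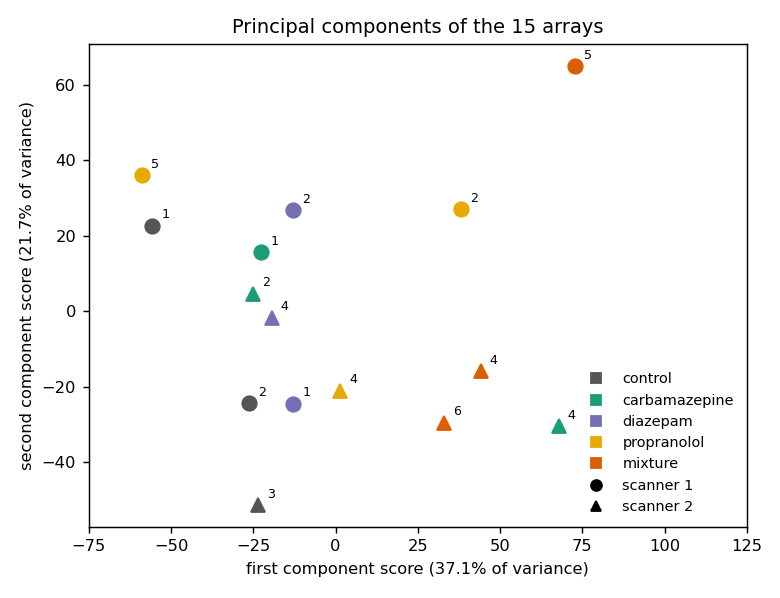
Scores of the 15 arrays on the first component (horizontal axis) and the second component (vertical axis), coloured by group, shaped by scanner and marked with the replicate number. The mixture arrays lie at 32.9 or above on the first component and the control arrays at -23.6 or below.

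In the comparison of the mixture with the control, the probe of smallest p was CUST_132559_PI429715507 (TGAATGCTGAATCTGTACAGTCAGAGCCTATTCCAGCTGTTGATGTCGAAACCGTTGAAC). Its log2 level was -0.99 ± 0.42 (SD, n = 3) in the mixture and -3.02 ± 0.54 (SD, n = 3) in the control, a log2 difference of 2.03 with a standard error of 0.29 (limma adjusted p = 0.175). CUST_86296_PI429715507 (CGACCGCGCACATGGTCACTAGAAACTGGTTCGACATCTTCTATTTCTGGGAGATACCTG) was not well above background on any control array and was well above it on all 12 exposed arrays. In the mixture it was higher than in the control by at least 8.25-fold, a bound for dim signal only (limma adjusted p = 0.205). Such bounds set the mean of the brighter group against, for each dim array, the higher of its lowest detected signal and the probe's own. They are not strict limits, here and wherever a fold is given as at least. Some signals above the lowest detected one were also not well above background. CUST_113634_PI429715507 (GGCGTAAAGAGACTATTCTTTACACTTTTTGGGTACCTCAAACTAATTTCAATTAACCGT) was not well above background on any mixture array, and the control was at least 3.01-fold brighter (limma adjusted p = 0.205). CUST_16528_PI429715507 (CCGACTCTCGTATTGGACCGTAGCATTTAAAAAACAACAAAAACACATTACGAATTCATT) had a log2 difference of -0.71 with a standard error of 0.16 (limma adjusted p = 0.205). All 4 kept their direction on each scanner, which was likely beforehand, since the same arrays had served to choose them. No probe passed the threshold with all 15 arrays in the limma fit. At an unadjusted p under 0.05 there were 729 probes higher and 868 lower, the largest number of the 4 exposures in this scaling, and 867 higher and 665 lower when scaled by the 75th percentile over all probes. With spike-in scaling the mixture had the smallest number (1364), and without mixture replicate 5 it had 1026 against 1049 for propranolol. The number ran from 1026 to 2214 with 1 array left out, and without control replicate 1 more probes were higher (594) than lower (504). It was 533 with replicate number as a fixed block. The groups did not overlap in 17.7% of the probes, against 10% by chance, and this share ran from 4.74% (mixture versus carbamazepine) to 15.8% (propranolol versus control) in the other comparisons of 2 groups.

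The planned fit of the 6 control and mixture arrays alone called 317 probes for the same comparison, 8 higher and 309 lower in the mixture. The smallest adjusted p in limma was 5.7e-04. With 1 array left out that fit called between 118 (without control replicate 2) and 345 (without mixture replicate 6). With scanner as a block it called 511, 190 higher and 321 lower, so the nearly one-sided direction did not hold there. Of the 309 lower probes, 130 were not well above background on any mixture array, 67 were on some and 112 on all 3. For those 112 the median log2 difference was -2.50. For the others the differences are bounds of the kind given above, which are not strict limits. With these the median over all 309 was a difference of 2.50. Of the 309, 308 did not overlap between the 2 groups, which their choice on these same 6 arrays nearly ensured. The residual SD of the 317 probes was 0.47 over the control and mixture arrays and 1.58 over the 9 single-drug arrays, while over all tested probes these medians were 0.35 and 0.30. Over the 308 lower probes with a value on every array, the median log2 difference from the control mean was -3.09 in mixture replicate 4, -3.17 in replicate 5 and -2.52 in replicate 6. It was -3.67 in carbamazepine replicate 4 and -3.06 in propranolol replicate 2. It was -1.28 in diazepam replicate 2, -0.73 in propranolol replicate 4 and -0.52 in diazepam replicate 1, and between -0.34 and 0.13 in the other single-drug arrays. These medians include signals not well above background. The count therefore depended on which arrays entered the fit.

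**Figure D2:**
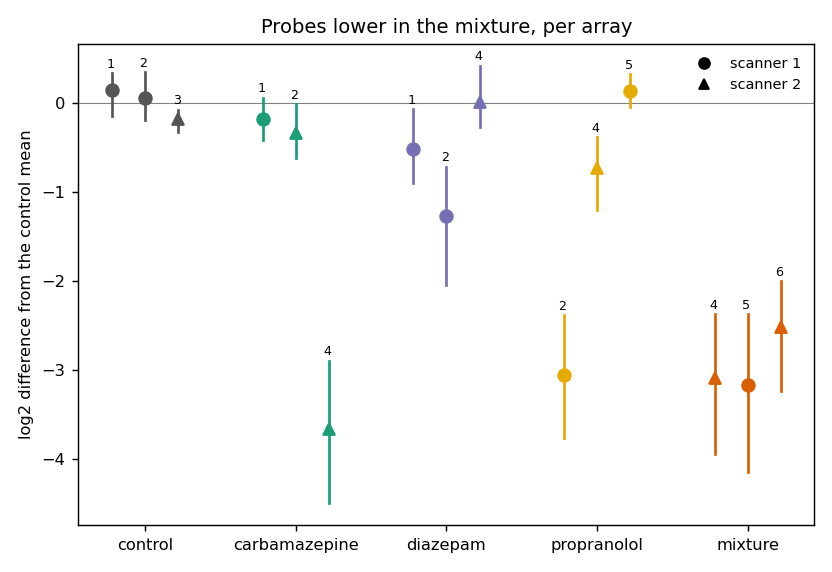
Log2 difference from the control mean of the 308 probes lower in the mixture, for each array (vertical axis), by group (horizontal axis). Points are medians over probes, bars run from the lower to the upper quartile, and digits are replicate numbers. The mixture arrays, carbamazepine replicate 4 and propranolol replicate 2 lie at -2.52 or below, and diazepam replicate 2 at -1.28. The probes were chosen on the mixture and control arrays.

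**Figure D3:**
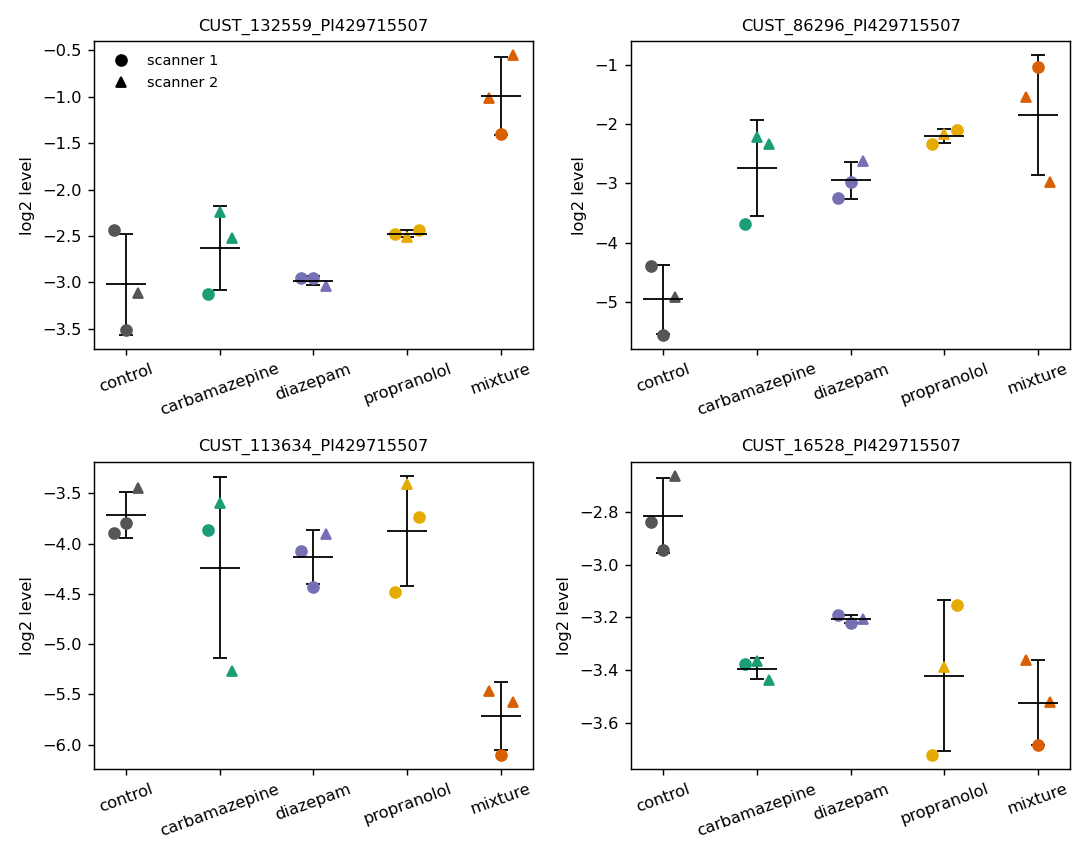
Log2 level of the 4 probes named for the mixture (vertical axes), by group (horizontal axes). Points are arrays shaped by scanner, and bars are the mean ± SD of 3 arrays. CUST_86296_PI429715507 lies between -5.55 and -4.40 in the control and at -3.68 or above in every exposed array.

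Carbamazepine against the control gave no probe past the threshold in limma, with 272 probes higher and 177 lower at an unadjusted p under 0.05. This balance turned without the filter on dim probes (513 higher and 1304 lower) and with slide as a block (767 and 929), and also without carbamazepine replicate 1 (281 and 328) or 2 (191 and 325). The number of such probes ran from 261 (without carbamazepine replicate 4) to 746 (without mixture replicate 5) when 1 array was left out. CUST_86296_PI429715507 was at least 4.44-fold higher, and CUST_19730_PI429715507 (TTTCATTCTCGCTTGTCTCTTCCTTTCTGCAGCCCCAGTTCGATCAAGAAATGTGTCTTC) at least 2.15-fold higher. CUST_19730_PI429715507 was well above background on 3 carbamazepine, 1 propranolol and 0 control, diazepam or mixture arrays, so only carbamazepine brought it through the filter. Its log2 level ran from -4.41 to -3.53 with carbamazepine and from -6.02 to -4.48 in the control. The bound is 1.11 on the log2 scale, and the fitted difference fell to 0.66 among the alternatives, so that this size is uncertain. CUST_76317_PI429715507 (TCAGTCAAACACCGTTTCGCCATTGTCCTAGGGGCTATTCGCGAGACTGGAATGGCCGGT) had a log2 difference of -1.16 with a standard error of 0.27. For CUST_67623_PI429715507 (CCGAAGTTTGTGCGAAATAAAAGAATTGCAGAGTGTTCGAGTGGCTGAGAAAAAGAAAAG) it was -0.72 with a standard error of 0.18. The limma adjusted p of these 4 was 1.00.

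Diazepam against the control gave no probe past the threshold in limma, with 196 probes higher and 236 lower at an unadjusted p under 0.05 (778 and 582 without the filter on dim probes). Leaving out 1 array gave from 297 (without control replicate 3) to 782 (without mixture replicate 5, 409 higher and 373 lower), and without control replicate 1 there were 200 higher and 113 lower. With scanner as a block 1 probe passed, CUST_149247_PI429715507 (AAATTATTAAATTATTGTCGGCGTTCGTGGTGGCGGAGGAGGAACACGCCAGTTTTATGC), which is named after its values were seen, with a log2 difference of -2.18 (limma adjusted p = 0.0378). CUST_86296_PI429715507 was at least 3.85-fold higher. CUST_18883_PI429715507 (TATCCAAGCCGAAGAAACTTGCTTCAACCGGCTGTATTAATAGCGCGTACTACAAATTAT) had a log2 difference of 1.04 with a standard error of 0.27, but it was not well above background on 1 of the 3 control arrays, so that this size is uncertain. CUST_18563_PI429715507 (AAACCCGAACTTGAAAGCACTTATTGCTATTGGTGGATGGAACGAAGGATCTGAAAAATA) had one of -1.24 with a standard error of 0.25. CUST_129391_PI429715507 (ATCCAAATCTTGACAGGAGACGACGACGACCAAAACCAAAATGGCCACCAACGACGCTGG) was not well above background on any diazepam array, and the control was at least 2.31-fold brighter. The limma adjusted p of these 4 was 0.999.

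Propranolol against the control gave no probe past the threshold in limma, with 443 probes higher and 249 lower at an unadjusted p under 0.05. This balance turned as for carbamazepine, to 756 higher and 1165 lower without the filter and to 637 and 689 with slide as a block. The count ran from 359 (without propranolol replicate 2) to 1049 (without mixture replicate 5) over the fits without 1 array, and it was 375 without control replicate 3. The smallest adjusted p was 0.704, held by CUST_14877_PI429715507 (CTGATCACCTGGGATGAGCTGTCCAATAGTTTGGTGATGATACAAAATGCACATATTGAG), whose log2 difference was 1.33 with a standard error of 0.23, and by CUST_86296_PI429715507, at least 6.47-fold higher. CUST_656_PI429715507 (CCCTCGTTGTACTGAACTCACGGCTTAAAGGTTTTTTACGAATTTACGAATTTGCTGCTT) had a log2 difference of -0.92 with a standard error of 0.19 (limma adjusted p = 0.722). CUST_18591_PI429715507 (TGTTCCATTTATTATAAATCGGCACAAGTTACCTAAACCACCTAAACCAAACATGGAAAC) was not well above background on any propranolol array, and the control was 1.69-fold brighter (limma adjusted p = 0.722). This is the fitted value and not a bound, and over the alternatives the log2 difference ran from -0.88 to -0.26.

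**Figure D4:**
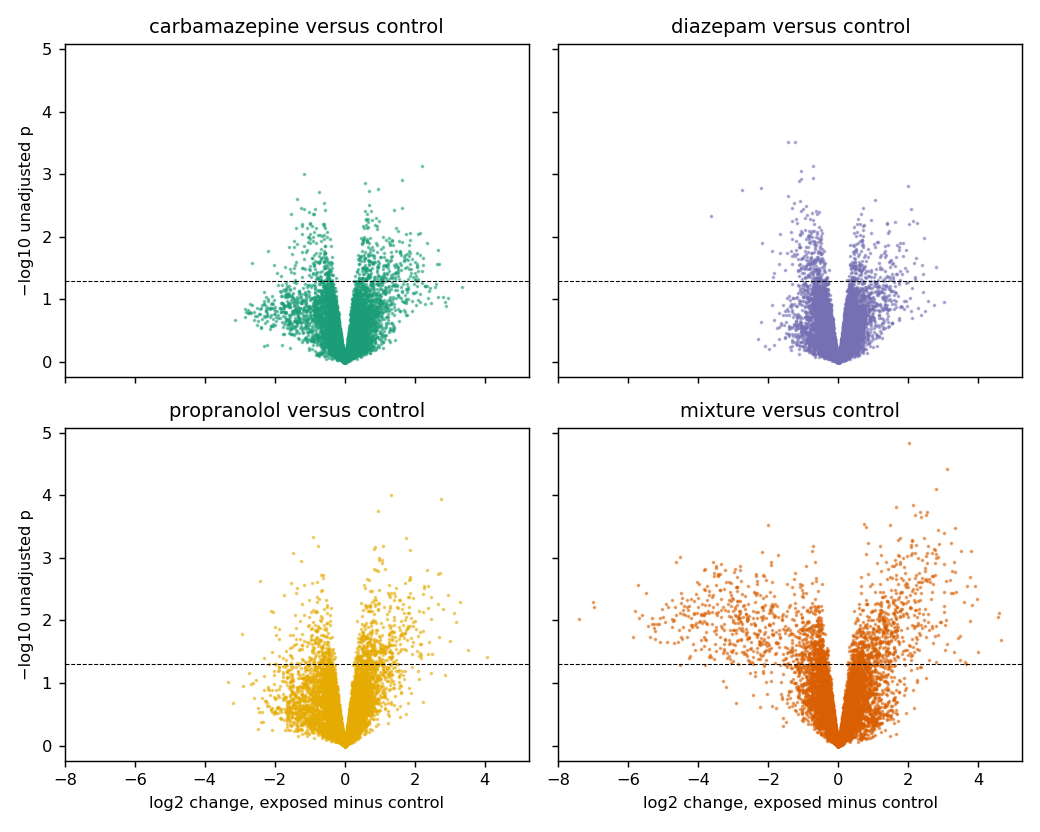
Log2 change against control (horizontal axis) and negative log10 of the unadjusted p (vertical axis) of the tested probes in the 4 exposures, from the limma fit of 15 arrays. The dashed line marks an unadjusted p of 0.05. No probe passed the adjusted threshold, and the mixture had the most probes above the line.

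The mixture was then compared with the mean of the single drugs. No probe passed the threshold in limma, with 252 probes higher and 600 lower at an unadjusted p under 0.05 (1227 and 845 without the filter on dim probes, and 4 and 5203 with spike-in scaling). Leaving out 1 array gave 563 to 1657 such probes. CUST_132559_PI429715507 again had the smallest p, with a log2 difference of 1.71 and a standard error of 0.24 (adjusted p = 0.131). CUST_73493_PI429715507 (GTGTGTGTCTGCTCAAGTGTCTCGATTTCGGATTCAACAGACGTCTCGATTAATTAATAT) had a log2 difference of 0.51 with a standard error of 0.12 (0.09 with spike-in scaling to 0.59 over the alternatives), and CUST_153468_PI429715507 (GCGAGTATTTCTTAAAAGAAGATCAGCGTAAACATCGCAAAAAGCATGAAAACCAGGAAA) one of -0.65 with a standard error of 0.13. CUST_113634_PI429715507 was 2.33-fold lower in the mixture by the bound described above. It was well above background on only 2 carbamazepine, 1 diazepam and 2 propranolol arrays, so that this size is uncertain. The limma adjusted p of these 3 was 0.643. Against carbamazepine, diazepam and propranolol alone the mixture gave 292, 1018 and 467 probes at an unadjusted p under 0.05 and 0 past the threshold. These counts were not stable. With 1 array left out they ran from 164 to 897, 604 to 1546 and 177 to 868, with slide as a block they were 203, 2149 and 176, and with spike-in scaling 2735, 4697 and 2751, nearly all lower in the mixture. Between the single drugs there were 338 such probes for carbamazepine and diazepam, 114 for carbamazepine and propranolol and 440 for diazepam and propranolol, with 0 past the threshold. Leave-one-out counts ran from 214 to 573, 76 to 301 and 253 to 749. These tests do not show that the drugs acted alike, since the median interval reached 0.60 to either side.

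The log2 changes of the 4 exposures were correlated across probes, which are not independent replicates. The highest correlation was 0.85 for carbamazepine and the mixture, and the lowest 0.60 for diazepam and the mixture. All share the 3 control arrays. Simulated unchanged groups that shared controls gave a mean correlation of 0.49 for carbamazepine and the mixture, with 95% of the simulations between -0.16 and 0.83. The correlation seen lay above that range, and 2 of 100 simulations gave one as high. That share takes no account of the choice of this pair as the highest of all pairs. The covariance was 0.354 against a simulated mean of 0.131, inside the range of 95% of the simulations (-0.037 to 0.374). Without carbamazepine replicate 4 this correlation was 0.47. For the other pairs at least 17 of 100 simulations gave a correlation as high. The 3 control arrays are too few to split, so part of any excess may come from sharing them.

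The arrays also carried spike-in probes for RNA added in the laboratory. The log2 ratio of endogenous to spike-in signal was -1.23 ± 0.20 in the control and -1.24 ± 0.09 in the mixture (SD, n = 3 each). It was -0.84 ± 0.17 with carbamazepine, -0.76 ± 0.06 with diazepam and -0.86 ± 0.21 with propranolol (SD, n = 3 each). Scaling to the spike-in probes moved the median log2 change by this difference, to 0.39, 0.47 and 0.36 for the 3 drugs and -0.05 for the mixture. With that scaling 0 probes passed the threshold in limma, and at an unadjusted p under 0.05 there were 1981 probes higher and 12 lower for carbamazepine, 3192 and 13 for diazepam, 1994 and 24 for propranolol, and 614 and 750 for the mixture. Changes given above are therefore relative to the bulk of the probes.

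**Figure D5:**
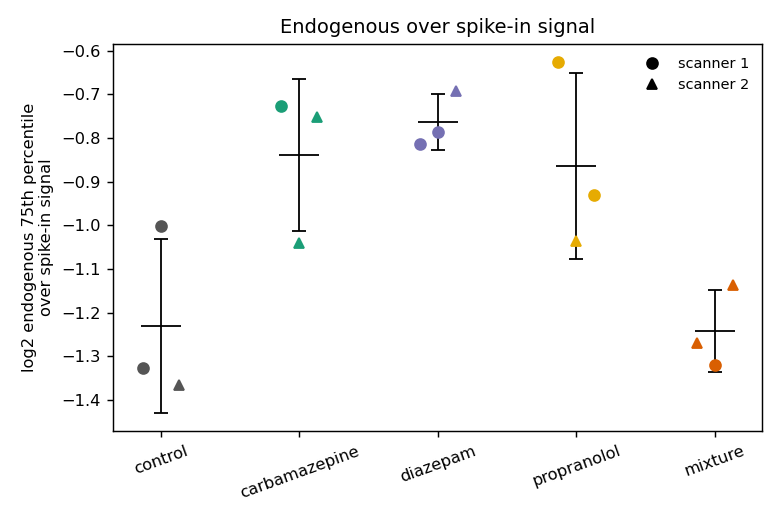
Log2 ratio of the 75th percentile of endogenous signal to the mean spike-in signal (vertical axis), by group (horizontal axis). Points are arrays shaped by scanner, and bars are the mean ± SD of 3 arrays. The control arrays lie between -1.37 and -1.002 and the diazepam arrays between -0.81 and -0.69.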

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

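The tests of scanner for the spike-in ratio were chosen only after the ratio was seen. The ratio of endogenous to spike-in signal lies outside the main measurement, and its mean in 3 groups was above the highest control array (-1.002): -0.84 with carbamazepine, -0.76 with diazepam and -0.86 with propranolol. Exact two-sided permutation tests against the control gave p = 0.2, 0.1 and 0.2 (adjusted p = 0.267 each), where 0.1 is the smallest possible. Several technical explanations are argued against. The single-drug arrays exceeded the others by at least 0.38 within each scanner and by 0.41 with slide as a block (95% interval 0.21 to 0.61). They did so by at least 0.40 with either the 2 dimmest or the 2 brightest of the 5 spike-in probes used. That check covers only the brightness range of these 5. The single drugs were pooled against control and mixture after the ratios were seen. The size and interval therefore do not test a drug effect, and ask only whether these technical terms remove the difference. Carbamazepine replicate 2 (-1.041) and propranolol replicate 4 (-1.036) lay below the highest control array. The amount of spike-in RNA added per sample was not measured and may account for the ratio, as may the share of messenger RNA in the total RNA, and neither was tested.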

How the results depend on the processing

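Among the alternatives, spike-in scaling, the 75th percentile over all probes, the authors' table without repeated values and all settings of the 6-array fit were chosen after seeing the data. All 20 probe comparisons taken by the naming rule, the mixture against the mean of the drugs included, kept their direction in every alternative run, but not their size. The rule chose them by direction and small p, and the alternatives reuse the same arrays, so a kept direction was likely beforehand. The log2 change of CUST_19730_PI429715507 with carbamazepine ran from 0.66 to 2.15, and that of CUST_67623_PI429715507 from -0.82 to -0.30. CUST_129391_PI429715507 with diazepam ran from -1.71 to -0.64, and CUST_113634_PI429715507 in mixture versus control from -2.12 to -0.81. The main counts are 0 in every comparison. The fit of only the groups compared gave 317 probes for mixture versus control and 0 for the other contrasts. The larger spread of these probes in the single-drug arrays (1.58 against 0.47) enters only the 15-array fit. In the 6-array fit, scanner as a block gave 511 probes, 294 of them shared, with 190 higher and 321 lower, so the direction was less one-sided than the 8 and 309 without it. Array weights gave 47 higher and 402 lower, and the authors' table gave 48 and 343. Leaving out 1 array gave 118 (without control replicate 2) to 345 (without mixture replicate 6), and it gave 131 without control replicate 1, 136 without control replicate 3 and 128 without mixture replicate 4. The other scalings gave 305 to 353 calls there, and 294 to 326 of these were lower in the mixture.

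The cause of the following changes was not tested. Scanner as a block gave 1 probe for diazepam versus control. The authors' table gave 24 for mixture versus control, all higher, 4 for diazepam versus propranolol, and 1 each for diazepam versus control, mixture versus diazepam and carbamazepine versus propranolol. Without its repeated values it gave 24 for mixture versus control and 1 each for diazepam versus control and mixture versus diazepam. Array weights gave 1 for mixture versus control and 1 for mixture versus the mean of the single drugs, the all-probe percentile 1 for the latter, each time CUST_132559_PI429715507, and spike-in scaling with scanner as a block 1 for mixture versus control. Leaving out each array gave 0 to 1 for both mixture comparisons and 0 to 5 for diazepam versus propranolol (5 without diazepam replicate 2). In mixture versus control, CUST_132559_PI429715507 passed in 5 of 32 alternatives and CUST_86296_PI429715507 in 4 of 31. CUST_113634_PI429715507 passed in 1 of 31 and CUST_16528_PI429715507 in 0 of 32. With slide as a block the correlation was 0.39 for carbamazepine and diazepam and 0.39 for diazepam and mixture. For carbamazepine and mixture it ranged from 0.47 to 0.87 with 1 array left out.

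Same-numbered samples did not deviate together: 7 of 16 pairs correlated above 0.1 (median -0.03), so the numbers were not taken as pairs. With the replicate block 0 probes passed in every comparison, fixed or random. The correlation limited to probes past the F test was not run because none passed, and the gene list tests were not run. Only 22.4% to 26.3% of probes were well above background, so changes in dimmer transcripts were not measurable.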

Other observations

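The tests of scanner and brightness for the first component, of the negative control bright on every array, and of probes dim in the control were chosen only after the result was seen. The 308 probes lower in the mixture moved as 1 set in arrays that had not been used to choose them. Over deviations from the group means in the 9 single-drug arrays, the median correlation between pairs of these probes was 0.90, against -0.01 to 0.02 in 100 random sets of the same size. Carbamazepine replicate 4 and propranolol replicate 2 weigh most in this correlation, with median log2 differences from the control mean of -3.67 and -3.06. The shift was graded: 308 of them were more than 2-fold below the control mean in carbamazepine replicate 4, 304 in propranolol replicate 2, 191 in diazepam replicate 2, 102 in propranolol replicate 4 and 58 in diazepam replicate 1. The scanner is argued against, since their SD with scanner in the fit was 1.70 against 0.25. Slide was not tested for this set. On slide 1 the median log2 difference from the control mean ran from -3.06 to 0.15 over the arrays. On slide 2 it ran from -3.17 to 0.06. Dim signal is argued against only for the 98 well above background on all 15 arrays, whose SD over the single-drug arrays was 1.40 against 0.25 for all such tested probes, and it stays open for the rest. Their median control level, 0.59 (log2) above that of all tested probes, decides nothing, since they were chosen for lying below the control. Of the 317 probes, 32.2% were well above background on all 15 arrays, against 71.6% of all tested, and their median log2 level was -2.88 against -2.29. A candidate explanation is a state of the animals or RNA that differed in degree between samples, strongest in the mixture samples and 2 others. Whether that state is an effect of exposure, of timing within the moult cycle or of sample handling was not tested, as the probes carry no gene names.

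In the first component the mixture arrays lay opposite the control arrays. With scanner in the fit 97.5% of the difference remained, and after removing a line on array brightness 87.3% remained. Without any 1 mixture array, the lowest mixture array stayed at least 46.2 above the highest control array. These values argue against scanner, brightness and a single mixture array as the whole cause. What else lies behind the component, slide included, was not tested.

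Splits of the same arrays that gave as large a count were counted for each comparison, the real split included. They were drawn without regard to scanner. For the 5 groups 40 of 100 drawn splits gave as many probes at an unadjusted p under 0.05 (560, highest other 1655), and for the mixture against the mean of the drugs 26 of 100 did (852, highest other 2405), so chance cannot be excluded. The 10 splits of 3 against 3 are too few for a share under 0.05. There the real count and the highest other were 449 and 768 for carbamazepine versus control (4 splits as large, the real one included), 432 and 603 for diazepam (5), 692 and 652 for propranolol (1) and 1597 and 1490 for the mixture (1). They were 292 and 1588 for mixture versus carbamazepine (10), 1018 and 1638 versus diazepam (7) and 467 and 2023 versus propranolol (8). Between drugs they were 338 and 1235 for carbamazepine and diazepam (7), 114 and 1443 for carbamazepine and propranolol (9) and 440 and 692 for diazepam and propranolol (5). The highest other split was the one that follows the scanner for carbamazepine and the mixture versus control (768 and 1490, where the next highest for the mixture was 917), mixture versus propranolol (2023), and carbamazepine versus diazepam (1235) and propranolol (1443). The last 3 are several times the real count, which points to a structure of the samples other than the groups. For mixture versus diazepam that split gave 1176. With scanner as a block the real counts were 686 for carbamazepine and 1962 for the mixture versus control, 529 and 1089 for the mixture versus propranolol and diazepam, and 373 and 127 for carbamazepine versus diazepam and propranolol. In the 6-array fit the real split called 317 probes and the highest other 0 (1 split as large).

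There were 5 probes not well above background on the 3 control arrays and well above it on all 12 exposed arrays, CUST_86296_PI429715507 among them. Of the 455 choices of 3 arrays, 24 gave as many (exact p = 0.0527, highest other 25), so chance cannot be excluded. With scanner added to the groups, 1021 probes differed between scanners at an adjusted p under 0.05 in limma. Scanner, software version and file layout coincide on every array, so their parts in this cannot be told apart.

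Tested probes with consecutive identifiers followed each other across arrays. The median correlation of their deviations was 0.44 over 849 pairs, 0.27 for identifiers 2 apart, 0.01 for 5 apart and -0.01 for random pairs, and 0.86 for 299 pairs of identical sequence. The hypothesis was that neighbours share target sequence. The 841 neighbours sharing no stretch of 20 bases had a median of 0.44, and only 8 shared one, too few to decide, so probes of one transcript at different places may account for it.

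A negative-control probe read 347810 on the array of diazepam replicate 1 and at most 64.2 on the others. Of the 2532 negative-control probes, 20 ranged over 100-fold between arrays. Outlier flags were not applied to control spots, so a fault of the spot on that array was not checked. Of the array probes, 0 shared 20 bases with this negative control. The hypothesis of cross-hybridisation with a probed transcript could not be decided, since 89.8% of the variance lay in that array and the highest correlation with an array probe was 0.98, as high as for shuffled profiles. For the negative control that ranged most among the 40 bright on every array (2.61-fold), it was 0.87 against 0.89 for shuffled profiles, and no array probe shared 20 bases with it. This does not decide either, since the correlation lay just below that limit and only the probed bases were searched.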
